A study of Homo sapiens with 3 samples.

How the data were processed

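Gene expression was measured in BE(2)-C cells, a human neuroblastoma cell line with an amplified MYCN gene, on Affymetrix HuGene-2_0-st arrays, which read whole transcripts with several probes per gene. Per the labels' protocols, cells received a control siRNA, WDR5 siRNA-1 or WDR5 siRNA-2 for 40 hours, total RNA was extracted with an RNeasy kit, and biotin-labelled cRNA was prepared. There were 3 groups with 1 array each, so no group had a replicate and no value has a replicate error. The number of arrays limits the precision of every value.

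The file used here is a value table deposited by the authors with 53617 rows, 1 per probe set, and 1 column per array. The deposited values were read as log2 from their range of 1.34 to 14.9. The file states no scale, and every fold given rests on that reading. The array medians were 5.81, 5.79 and 5.79 for control, siRNA-1 and siRNA-2, and no further scaling was applied. The values are levels per array, not centred on each gene. The submitters' processing notes name MAS5 without saying which step it did. The background correction, the normalization and the way probes were summarised are otherwise not given in the sources used here. On all 3 arrays the same value stood in 37.1% of rows, and at least 2 arrays shared an exact value in 64.7% of rows, so many small differences between arrays appear as an exact 0. The 23 background rows of the array, grouped by the GC content of their probes from 3 to 25 GC bases, ranged from 1.75 to 9.26. Their median over the 3 arrays was 4.61. With so wide a range, a level alone does not tell whether a gene was above background, and no detection call was made.

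Probe sets were named through the platform annotation provided with the data, in which 16098 rows had 1 gene symbol, 0 had several and 37519 had none here (190 of these are control rows). The Entrez identifiers of all 16098 were found in the RefSeq gene table of the GRCh38.p14 assembly, which gave current symbols and biotypes. No genome build is named for the value table, so no coordinates are given. MYCN itself and MDM2 were not analysed here. Of a gene's several probe sets (779 genes) the one with the highest mean over the 3 arrays was used, which gave 14884 genes. The 7442 genes (6866 of them protein-coding) whose mean log2 value was at or above the median, 6.78, were kept.

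The log2 ratio of each WDR5 siRNA to the control was computed per gene, and a gene was counted when it was at least 1.5-fold from control in the same direction with both siRNAs. With 1 array per group no p-value was computed for these counts. As yardsticks, the same rule was applied with each of the 3 arrays set against the other 2, and 1000 sets of 3 unchanged arrays were simulated. Their noise was drawn from the differences between the siRNA-1 and siRNA-2 arrays in 20 bins of expression, so it includes any real difference between the siRNAs. Both ratios share the 1 control array, which makes them correlate without any effect, and a single control cannot be split. For 25 gene lists, the median log2 ratio was placed among 10000 random lists of the same size matched on mean level in 20 bins. These percentiles describe these arrays and are not p-values. As a no-change value, added after the results were seen, the lists were also scored in 100 such simulations, each against 1000 random lists, with the noise of each gene drawn independently. Lists with at least 5 kept members were scored (22 lists). The replication-dependent histones had 0 measured members, and the Schwann and stromal markers (2 kept) and the leukocyte and endothelial markers (1 kept) had too few.

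The comparisons, the 25 lists, the thresholds and the alternatives named below were fixed before the data were examined. Alternatives, lists and tests added later are identified as such where they are reported. The lists were written from general knowledge. CCNE1 and MDM2 were partly put on them from what is remembered of this study, so the place of CCNE1 is not independent evidence. The genes named are WDR5, the 12 genes with the highest and the 12 with the lowest shared change (ranked by the smaller of the 2 absolute log2 ratios), up to 4 members of each list by the same ranking, and the 5 genes with the highest and the 5 with the lowest ratio between the siRNAs. Small RNA genes, olfactory receptors, open reading frame names, LINC and LOC names and antisense transcripts were counted but not named. Genes named outside this rule are identified as chosen after their values were seen.

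The counting rule was tested on simulated data of 7442 genes with 200 changed genes. It recovered 37.3% of the genes changed 1.5-fold, 86.6% of those changed 2-fold and 95.5% of those changed 3-fold with both siRNAs, and it called 238 unchanged genes, 3.29% of them, at a noise as large as the difference between the siRNA arrays. The real arrays gave only 109 called genes in all, so these shares are not the error rates of the rule on the real arrays. A list of 40 genes shifted by -0.3 came out below every random list, and 14 of 200 unshifted lists came out beyond the central 95%. Alternatives were quantile normalization, centring each array on its median, no filter or a filter at the 75th percentile, the mean of a gene's probe sets, thresholds of 2-fold and 1.3-fold, other list statistics, and limma with both WDR5 siRNA arrays as 1 arm. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, R 4.3.3 and limma 3.58.1 were used.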

Results

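Expression was profiled in 3 cultures of the neuroblastoma line BE(2)-C, 40 hours after transfection with a control siRNA or with 1 of 2 siRNAs against WDR5. WDR5 is a core subunit of the complexes that methylate histone H3 at lysine 4. Each condition was represented by 1 array with 53617 probe sets, of which 7442 named genes were kept. Without replicates, the values below carry no error, and each ratio compares a pair of arrays rather than conditions. The deposited log2 values of the arrays had a Pearson correlation across probe sets, which are not independent replicates, of 0.991 between siRNA-1 and control, 0.992 between siRNA-2 and control, and 0.990 between the siRNAs.

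The targeted transcript was lower with both siRNAs. WDR5 stood at a log2 value of 9.46 with the control siRNA and at 7.90 with each WDR5 siRNA, a log2 ratio of -1.56, or 2.95-fold lower (33.9% of control). The level of 7.90 was above the filter level of 6.78 but within the range of the background rows, which reached 9.26. The size of the WDR5 fold is therefore uncertain too. Among the genes lower with both siRNAs, WDR5 had the second lowest shared ratio. The identical value in the siRNA-1 and siRNA-2 arrays is 1 of the exact ties found throughout the table, since 21.5% of kept genes had the same value on these arrays.

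The first question was which genes differed from control with both siRNAs. Of the 7442 genes, 46 were at least 1.5-fold higher and 63 at least 1.5-fold lower with both. The excess of lower genes was absent with quantile normalization (51 higher and 51 lower) and with the 75th percentile filter (33 higher and 30 lower). The lowest was CCNE1, the gene of cyclin E1, which drives entry into S phase: it was 3.43-fold lower with siRNA-1 and 5.23-fold lower with siRNA-2. CCNE1 then stood at 6.59 and 5.98, below the filter level of 6.78 and within the range of the background rows, so the size of its fold is uncertain. After WDR5 came CERK (ceramide kinase), 2.44-fold and 2.35-fold lower, EMP2 (an epithelial membrane protein), 2.32-fold and 2.31-fold lower, and SEPTIN14 and RTKN2, with log2 ratios of -1.29 and -1.19 and of -1.11 and -1.11 for siRNA-1 and siRNA-2. The long noncoding snoRNA host transcript SNHG15 was 2.01-fold and 2.15-fold lower. IGFBP5, which encodes an insulin-like growth factor binding protein, was 2.76-fold and 1.97-fold lower, and DPYSL5, a neuronal growth cone protein gene, was 2.22-fold and 1.97-fold lower. DDHD2, EFR3B and SCCPDH completed the 12 lowest, with ratios from -1.34 (SCCPDH with siRNA-1) to -0.83 (SCCPDH with siRNA-2). Like CCNE1, SEPTIN14 (6.68 and 6.777) and EFR3B (6.48 and 6.71) stood below the filter level with both siRNAs, so their folds are also uncertain. CERK alone among the 12 stayed above the highest background row (9.26) with both siRNAs.

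The highest shared ratio belonged to EGR1, an immediate-early zinc finger transcription factor gene, which was 4.15-fold higher with siRNA-1 and 3.78-fold higher with siRNA-2. KPNA5, an importin alpha gene, was 2.73-fold higher with each, and SMIM15 was 3.08-fold and 2.37-fold higher. VGF, a neurotrophin-responsive neuropeptide precursor gene, was 2.36-fold and 2.21-fold higher. CSGALNACT2, an enzyme of chondroitin sulfate synthesis, had log2 ratios of 1.09 and 1.29, and STXBP5 (tomosyn, a regulator of vesicle fusion) of 1.02 and 1.47. LUM (lumican, a proteoglycan) was 2.87-fold and 1.97-fold higher, and TIMP3, a metalloproteinase inhibitor, was 1.87-fold and 2.07-fold higher. ARL6, CHIC1, PLK2 (a polo-like kinase gene) and SLC51B completed the list, with the smaller ratio of each between 0.89 and 0.97. TIMP3 was the exception in robustness, since the mean of its probe sets gave a smaller shared ratio of 0.45, below 1.5-fold.

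**Figure D1:**
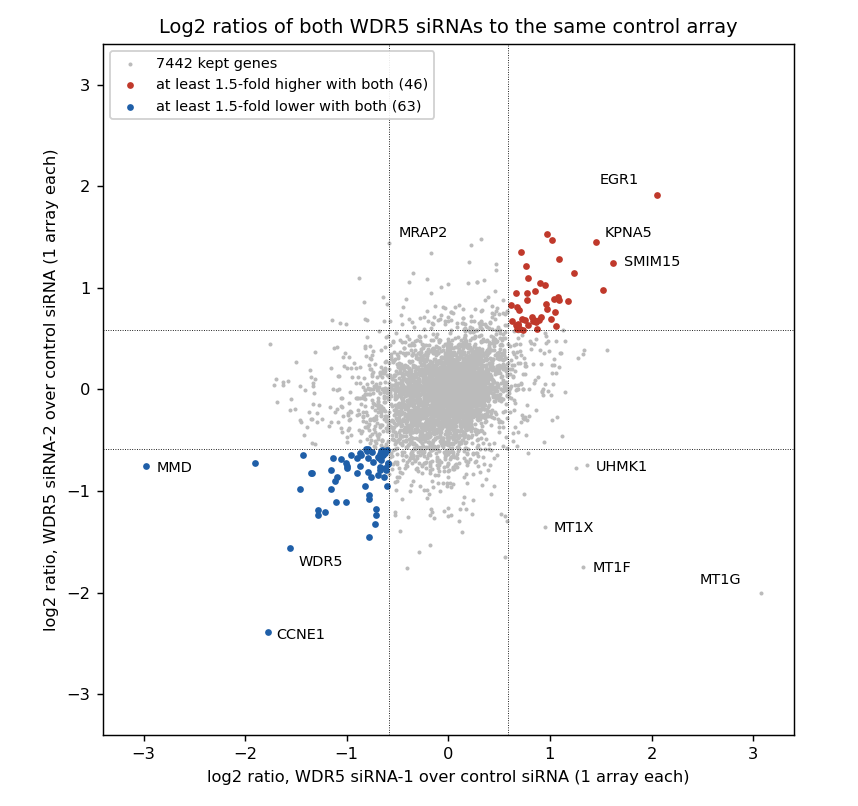
Log2 ratio of WDR5 siRNA-1 (x axis) and WDR5 siRNA-2 (y axis) over the same control array, 1 point per kept gene (7442), with dotted lines at 1.5-fold. The 46 red genes were higher and the 63 blue genes lower with both siRNAs, with EGR1 and CCNE1 at the ends, while MT1G, MT1F and MT1X lie in the quadrant of opposite ratios.

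No replicate test stands behind these counts, so they were set against the other ways to divide the arrays. The control array was at least 1.5-fold apart from both others in 109 genes, the siRNA-1 array in 258 and the siRNA-2 array in 209, so the arrays of the WDR5 siRNAs each stood apart from the rest in more genes than the control did. Simulated unchanged arrays that vary as much as the siRNA arrays differ from each other gave on average 118 higher and 118 lower genes with both, more than the 46 and 63 observed. For siRNA-1 alone they gave 342 higher and 341 lower genes, against 167 and 342 observed. For siRNA-2 alone they gave 341 and 341, against 163 and 298. The simulation thus overshot the higher genes of each siRNA. It also overshot the lower genes of siRNA-2, for which the central 95% of simulations ran from 306 to 377. An overlap smaller than simulated therefore does not mean one below chance. Independent lists of the observed sizes would share 3.66 higher and 13.7 lower genes, but this figure leaves out the shared control. Across genes, the siRNA ratios had a Pearson r of 0.286 and a Spearman rho of 0.251, against a simulated r of 0.50 with no effect (0.472 to 0.527 in the central 95% of simulations). Their covariance was 0.0247 and the simulated one 0.0624, a difference of -0.0376. The simulated noise includes any real difference between the siRNAs, so it may overstate chance, and part of the observed overlap may come from the shared control. With both siRNA arrays as 1 arm, limma called 0 genes at an adjusted p under 0.05 and 660 at an unadjusted p under 0.05 (for WDR5 the adjusted p was 0.226). Of these 660 genes, 337, WDR5 among them, had exactly tied siRNA arrays, so their p rests on a tie rather than on a measured spread. In simulated arrays limma called 0 of the 200 changed genes.

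**Figure D2:**
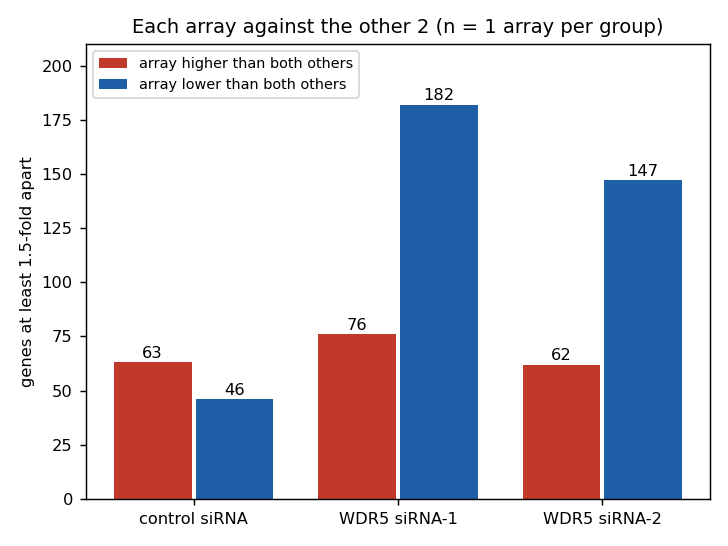
Number of genes (y axis) at least 1.5-fold higher or lower on 1 array than on both others, for each of the 3 arrays. The control array stood above both others in 63 genes and below both in 46, while the siRNA-1 array stood below both in 182 and the siRNA-2 array in 147.

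The second question was whether groups of genes with a common function lay to 1 side of control. Of the 22 lists scored, 3 had a median beyond the central 95% of matched random lists with both siRNAs, and all 3 were on the low side: cytoplasmic ribosomal proteins, DNA replication and S phase, and mitosis and G2/M. For each siRNA alone, 5 lists were beyond that range with siRNA-1 and 10 with siRNA-2. In 100 simulations of unchanged arrays sharing 1 control, 0.99 and 1.09 of the 22 lists were beyond it on average, and 0.14 with both (at most 2). That simulation lets list members vary independently, which genes of a common function need not do, and cannot stand in for a second control array. Its ratios are also centred on 0, whereas the kept genes had mean log2 ratios of -0.023 with siRNA-1 and -0.035 with siRNA-2. It was not matched to the exact ties either, so the simulated counts of lower genes given below are rough.

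Genes of cytoplasmic ribosomal proteins had a median log2 ratio of -0.30 with siRNA-1 and -0.35 with siRNA-2, below all 10000 random lists in both cases. Of the 79 listed genes, 46 were measured. Of the 45 kept members, 6 were at least 1.5-fold lower with both siRNAs, 0 were higher by as much and 39 met neither limit; 32 were lower with both by any amount and 5 higher, against 13.9 lower on average (at most 20) in the simulated arrays. RPL36 was 1.73-fold and 1.76-fold lower, RPL34 1.71-fold and 2.12-fold, and RPL29 2.08-fold and 1.61-fold, while RPL37A had log2 ratios of -0.68 and -0.76. Ribosomal protein genes have many near-identical processed pseudogenes, so single values are uncertain. The median level of the list, 8.69, was close to the kept-gene medians of 8.51 to 8.56. The 6 members at 1.5-fold had control levels of 7.66 to 10.7. The members with the highest control levels, 12.02 to 13.72, were chosen after their values were seen and differed in direction. RPL10 (0 and 0), RPS19 (0.12 and 0.07) and RPL19 (0.21 and 0.04) were not lower with either siRNA. RPS27 (-0.44 and 0.12) and RPS28 (0.09 and -0.05) were mixed. RPL41 (-0.41 and -0.41), RPS15 (-0.297 and -0.484) and RPL12 (-0.05 and -0.16) were lower with both. The mitochondrial ribosomal protein genes, 55 of them, had medians of 0.08 and 0.00, at percentiles 99.9 and 56.9, and 0 members at 1.5-fold with both. MRPS5, the member with the largest shared ratio, was 1.46-fold and 1.23-fold higher.

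Cell cycle genes were lower as groups. The 31 kept genes of DNA replication and S phase had medians of -0.18 with siRNA-1 and -0.44 with siRNA-2, at percentiles 0.01 and 0, and 26 were lower with both by any amount and 0 higher, against 9.99 lower on average (at most 18) in the simulated arrays. Besides CCNE1, E2F1, the transcription factor gene of the G1 to S transition, was at least 1.5-fold lower with both (log2 ratios of -1.14 and -0.68). Its relative E2F2 had log2 ratios of -0.96 and -0.45, and the exonuclease gene EXO1 of -0.51 and -0.44. The list's median of siRNA-1 over siRNA-2 was 0.24, which was not tested, whereas E2F1, E2F2 and EXO1 were lower with siRNA-1 than with siRNA-2. The members not lower with both, GINS1, GINS3, GINS4, CDC45 and CCNE2, were higher than control with siRNA-1 and lower with siRNA-2. Those members were chosen after their values were seen. The 34 kept genes of mitosis and G2/M had medians of -0.14 and -0.25, at percentiles 0.01 and 0, with 25 lower with both and 0 higher by any amount, against 10.9 lower on average (at most 18) in the simulated arrays. KIF14, a mitotic kinesin gene, was 1.56-fold and 1.52-fold lower and alone passed the limit with both. KIF2C (-0.64 and -0.57), NUSAP1 (-0.69 and -0.47) and PTTG1 (-0.32 and -0.59) came next.

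**Figure D3:**
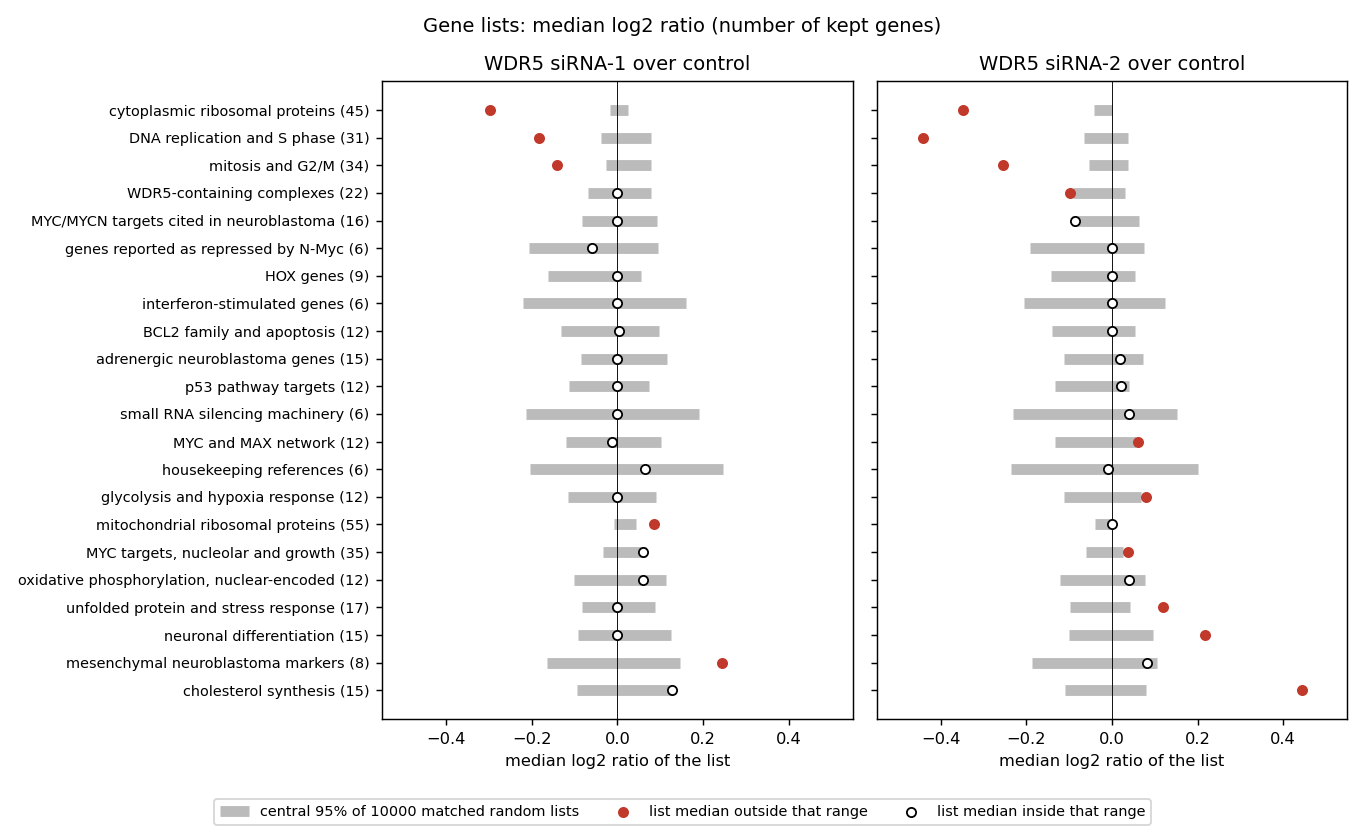
Median log2 ratio over control (x axis) of the 22 scored gene lists for each siRNA, with the central 95% of 10000 random lists matched on level in grey and the number of kept genes in brackets. Filled points lie beyond that range: cytoplasmic ribosomal proteins (-0.30 and -0.35), S phase (-0.18 and -0.44) and mitosis (-0.14 and -0.25) do so on the low side with both siRNAs. Cholesterol synthesis (0.13 and 0.44) does so on the high side with siRNA-2 and lies at the edge of the range with siRNA-1.

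**Figure D4:**
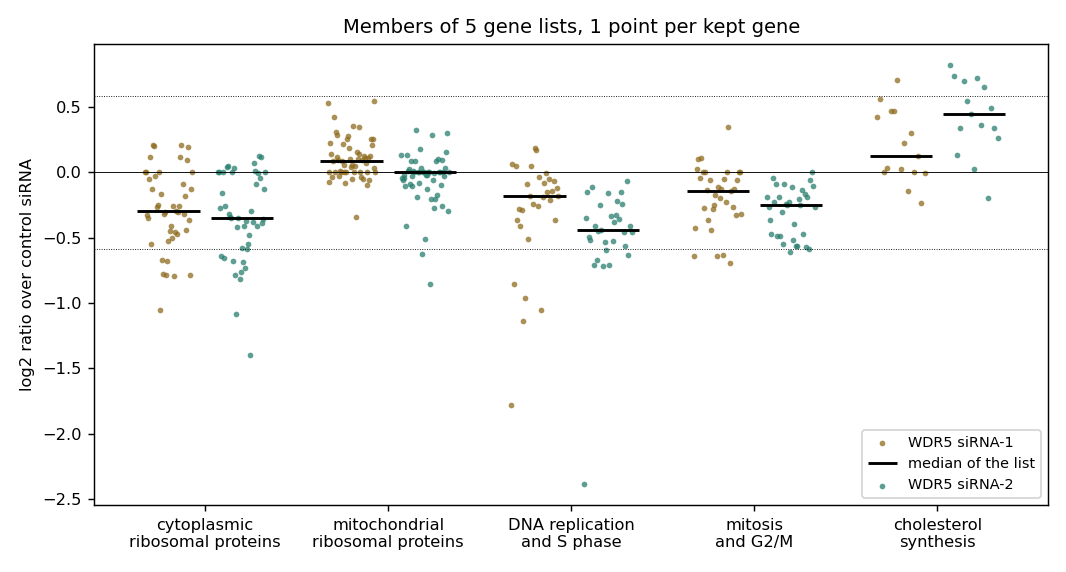
Log2 ratio over control (y axis) of each kept member of 5 lists, with siRNA-1 and siRNA-2 side by side, black bars at the list medians and dotted lines at 1.5-fold. Most ribosomal protein and cell cycle members lie below 0 with both siRNAs, and CCNE1 is the lowest point (-1.78 and -2.39).

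The series sets WDR5 beside N-Myc, the product of MYCN, so lists of MYC-related genes were examined. The nucleolar and growth targets of MYC were not lower: their 35 kept members had medians of 0.06 with siRNA-1 and 0.04 with siRNA-2, at percentiles 96.8 and 98.3 of the random lists, and 0 members were at 1.5-fold with both. The call for siRNA-2 was lost with the 75th percentile filter (0.0339) and with the list mean (0.0265). SRM (spermidine synthase) was 1.43-fold and 1.23-fold higher, and LAS1L, a ribosome maturation gene, was 1.22-fold and 1.33-fold lower. Among 16 kept MYC and MYCN targets often cited in neuroblastoma, the medians were 0.00 and -0.09, at percentiles 43.7 and 2.87. In that list 2 genes, CCNE1 and E2F1, were at least 1.5-fold lower with both (CCNE1 was listed partly from what is remembered of this study, so it is not independent evidence), 14 met neither limit, and the mean of the list (-0.38 and -0.28) lay at percentiles 0.02 and 0.07. Without CCNE1 the mean was -0.28 with siRNA-1, at percentile 0.21, and -0.14 with siRNA-2, at percentile 5.98, within the random range. CCNE1, E2F1, CDC25A and MCM7 are also on the S phase list and AURKA on the mitosis list. Members of the nucleolar list such as MCM4 and PLK4 are shared with these lists too, so the MYC and cell cycle lists are not independent. LDHA (lactate dehydrogenase A) had ratios of -0.61 and -0.57 and AURKA (Aurora kinase A) of -0.64 and -0.19. The 12 kept genes of the MYC and MAX network had medians of -0.01 and 0.06, at percentiles 21.2 and 97.8, and 0 members passed with both; the call for siRNA-2 was lost with no filter, with the 75th percentile filter, with the mean of probe sets, with the list mean and with unmatched lists. The 6 kept genes reported as repressed by N-Myc had medians of -0.06 and 0.00, and CLU (clusterin) was 1.38-fold and 1.26-fold lower.

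Subunits of the WDR5-containing complexes had medians of 0.00 and -0.10 over 22 kept genes, the second at percentile 2.05. Without WDR5 this became -0.06, at percentile 6.91, and the call was also lost with the 75th percentile filter (-0.0646). HCFC1 was 1.24-fold lower with each siRNA, KAT8 1.16-fold lower with each, and MEN1 (menin) 1.54-fold and 1.16-fold lower.

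Genes of cholesterol synthesis lay on the high side. The 15 kept members had medians of 0.13 with siRNA-1, at the edge of the random range (percentile 97.495), and 0.44 with siRNA-2, above all random lists; 11 were higher with both by any amount and 0 lower, but 0 reached 1.5-fold with both. DHCR7 was 1.47-fold and 1.67-fold higher, HMGCS1 1.38-fold and 1.62-fold, IDI1 1.39-fold and 1.46-fold, and INSIG1, a sterol sensor gene, 1.63-fold and 1.36-fold. The median of siRNA-1 over siRNA-2 was -0.26, which was not tested.

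Neuronal differentiation genes had a median of 0.00 over 15 kept members with siRNA-1 and of 0.22 with siRNA-2 (percentile 99.97, and 96.9 with no filter). Besides VGF, RET, a receptor tyrosine kinase gene, was 1.25-fold and 2.80-fold higher, while GAP43 had log2 ratios of -0.97 and -0.29. Mesenchymal neuroblastoma markers had medians of 0.24 and 0.08 over 8 kept members, at percentiles 99.7 and 96.0; LUM was the 1 member at 1.5-fold with both, and with no filter the siRNA-1 median was 0. Adrenergic neuroblastoma genes, 15 kept, had medians of 0.00 and 0.02, with ISL1 1.17-fold and 1.31-fold higher and MEIS2 1.22-fold lower with each. Of 12 kept p53 targets, with medians of 0.00 and 0.02, PLK2 alone passed with both. The 12 kept BCL2 family and apoptosis genes (0.00 and 0.00) and the 6 kept interferon-stimulated genes (0.00 and 0.00) had 0 members at 1.5-fold with both, and IFI35 was 1.38-fold higher with each.

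Further lists were near 0 with siRNA-1 and beyond the random range with siRNA-2. The unfolded protein and stress response had medians of 0.00 and 0.12 (17 kept, percentile 99.8 with siRNA-2). CREB3L2 had log2 ratios of 0.28 and 0.25, ATF3 of 0.12 and 0.12, and DDIT4 of 0.09 and 0.29. PHGDH, a serine synthesis gene on that list, went the other way, 2.92-fold lower with siRNA-1 and 1.06-fold lower with siRNA-2. Glycolysis and hypoxia genes had medians of 0.00 and 0.08 (12 kept, percentile 98.1 with siRNA-2). The glycolysis call was lost with no filter (0.0277), with the 75th percentile filter (0.12) and with the list mean (0.0503), and the stress response call with the 75th percentile filter (0.079). Nuclear-encoded oxidative phosphorylation genes (0.06 and 0.04), HOX genes (0.00 and 0.00), small RNA silencing genes (0.00 and 0.04) and housekeeping references (0.06 and -0.01) lay within the range with both. Markers of cells other than neuroblastoma gave little to compare: S100B and SOX10, of Schwann cells, had ratios of 0.00 with both siRNAs, and CD68, of macrophages, had log2 ratios of 0.38 and 0.08.

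The third comparison was between the siRNAs. With siRNA-1, 167 genes were at least 1.5-fold higher than control and 342 lower; with siRNA-2, 163 were higher and 298 lower. Directly compared, 313 genes were at least 1.5-fold higher and 346 lower with siRNA-1 than with siRNA-2. Metallothionein genes, which encode small metal-binding proteins, led the difference: MT1G was 33.8-fold, MT1F 8.41-fold and MT1X 4.92-fold higher with siRNA-1 than with siRNA-2. MT1G stood at 5.36 with siRNA-2, below the filter level of 6.78 and within the range of the background rows, so the size of its fold is uncertain. These genes are close paralogs whose probes can read each other. TMEM30A (a subunit of phospholipid flippases) was 4.65-fold and the kinase gene UHMK1 4.32-fold higher with siRNA-1. At the other end, MMD was 4.66-fold lower with siRNA-1 than with siRNA-2, and it was lower than control with both (7.87-fold and 1.69-fold). ERG28, a sterol synthesis scaffold gene, was 4.59-fold lower with siRNA-1 than with siRNA-2, MRAP2, a melanocortin receptor accessory protein gene, 4.07-fold lower, LRRTM1, a synaptic adhesion gene, 3.92-fold lower, and KIF3B, a kinesin motor gene, 3.53-fold lower. With 1 array each, no test of these differences was possible, and the sequences of the siRNAs were not used here.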

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

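The metallothionein list and the test of noise on it were chosen after MT1G, MT1F and MT1X had been seen. The differences below were not tested, as each siRNA had 1 array.

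Opposite directions against control, each at 1.5-fold or more, were seen in 6 of the genes named. Log2 ratios with siRNA-1 and siRNA-2 were 3.08 and -2.0 for MT1G, 1.33 and -1.75 for MT1F, 0.95 and -1.35 for MT1X, 1.36 and -0.75 for UHMK1, -0.88 and 1.09 for LRRTM1, and -1.14 and 0.68 for KIF3B. Among all kept genes, 7 were higher with siRNA-1 and lower with siRNA-2, and 10 the reverse.

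Some but not all metallothioneins shared this pattern. MT2A, not named by the ranking, had ratios of 0.53 and -0.56, while MT1E was tied at 6.85 on all arrays and MT4 had ratios of 0.03 and 0.12. Of 11 measured members 36.4% were at least 1.5-fold higher with siRNA-1 than with siRNA-2, and of the 6 kept members 66.7%, against 4.21% of all kept genes. The list was put together around 3 of the 4 genes counted, 5 of the 11 measured members lay below the level filter, and each siRNA had 1 array, so array noise remains open. A difference between the transfections, in the siRNA or in the culture, was not tested. A test on SLC30A1, a zinc exporter gene, was planned for this but could not be run, as the gene was not among those measured here.

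Probe sets without a gene name here, which the report does not use, also differed: of 8846 at the same level filter, 278 were at least 1.5-fold from control in the same direction with both siRNAs (84 higher and 194 lower), against 410 for the siRNA-1 array and 376 for the siRNA-2 array set apart from the others. The most extreme were 16855176 (-1.86 and -1.97) and 17117665 (-1.96 and -1.81) on the low side, and 16876726 (1.89 and 1.37) and 16852463 (1.37 and 1.61) on the high side.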

How the results depend on the processing

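No paired analysis was possible because each group had 1 array, and no replicate could be left out. The pseudocount alternative was not run, since the deposited values are already logarithms. The lists without WDR5 and CCNE1 (median and mean), the genes with no tied arrays and the protein-coding genes were alternatives chosen after seeing the data. The 3 lists low with both siRNAs kept their direction and call under the scalings, filters, probe set rule and list statistics run on them. WDR5 and the genes named for a shared or between-siRNA difference, other than TIMP3, kept theirs under quantile normalization, median centring and the mean of probe sets; members named from the lists were not rerun singly. With quantile normalization 51 genes were higher and 51 lower with both, and the scalings moved the median of kept genes by at most 0.0505. Of the list results under all alternatives, 282 were unchanged in their call, 12 gained a call and 16 lost it; the causes were not tested.

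Counts followed the threshold by construction. At 2-fold, 6 genes were higher and 7 lower with both siRNAs; 39 and 83 with siRNA-1, 29 and 49 with siRNA-2; 70 were higher and 97 lower with siRNA-1 than siRNA-2; and 13, 55 and 39 set the control, siRNA-1 and siRNA-2 arrays apart. At 1.3-fold, in the same order, these were 134 and 197; 442 and 713; 374 and 654; 726 and 704; and 331, 637 and 524. With the 75th percentile filter, which tested 3721 genes, 33 genes were higher and 30 lower with both, so the excess of lower genes turned, 98 higher and 181 lower with siRNA-1, 154 lower with siRNA-2, 168 higher and 206 lower with siRNA-1 than siRNA-2, and 63, 148 and 119 set each array apart. The control array had the fewest genes apart under every one of these settings. limma, with the lone control assumed to vary like the siRNA arrays, called 0 higher and 0 lower.

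List calls that changed were these medians. Quantile normalization put the mesenchymal markers with siRNA-2 (0.16) and cholesterol synthesis with siRNA-1 (0.14) beyond the range. With no filter, calls ended for siRNA-2 in the MYC and MAX network (0.007), neuronal differentiation (0.0477) and glycolysis (0.0277), and for siRNA-1 in the mesenchymal markers (0). With the 75th percentile filter, calls ended for siRNA-2 in the WDR5 complexes (-0.0646), the MYC and MAX network (0.13), the nucleolar MYC targets (0.0339), the unfolded protein response (0.079) and glycolysis (0.12), and began in the MYC and MAX network with siRNA-1 (-0.23), the adrenergic genes with siRNA-2 (0.16) and cholesterol synthesis with siRNA-1 (0.26). The mean of probe sets ended the call of the MYC and MAX network with siRNA-2 (0.0578). List means in place of medians ended calls with siRNA-2 in the MYC and MAX network (0.0778), nucleolar MYC targets (0.0265) and glycolysis (0.0503), and made calls in the cited MYC and MYCN targets (-0.38 and -0.28), the p53 targets with siRNA-2 (0.14) and cholesterol synthesis with siRNA-1 (0.20). Unmatched random lists ended the call of the MYC and MAX network with siRNA-2 (0.0597) and made calls in nucleolar MYC targets (0.0605) and cholesterol synthesis (0.13) with siRNA-1. Leaving WDR5 out ended the call of the WDR5 complexes with siRNA-2 (median -0.0646, mean -0.1183), and the mean of the cited MYC and MYCN targets without CCNE1 made a call with siRNA-1 (-0.2827) and none with siRNA-2 (-0.1379). The highest background row reached 9.26, above the median level of kept genes, while the median of the background rows was 4.61, below the filter level of 6.78. Low-level genes may still be background on these arrays.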

Other observations

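The immediate-early genes and the tests of quantile normalization, of ties above background, of short transcripts and of the control array were chosen after related values had been seen.

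Beside EGR1, other immediate-early and MAPK feedback genes were looked at. Of 15 kept genes, 9 were higher, 1 lower and the others neither with both siRNAs by any amount, and besides EGR1 JUNB was at least 1.5-fold higher with both (0.78 and 0.95). ARC had ratios of 0.48 and 0.80, SPRY4 of 0.28 and 0.58 and DUSP4 of 0.91 and 0.25, IER3 was lower (-0.12 and -0.12), ETV4 had opposite ratios of -0.31 and 0.34, and FOS, IER2 and KLF6 were tied at the control value. Most of these values had been seen when the genes were put together, so no statement about them as a group is made.

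Exact ties between arrays were the most unusual feature of the table. In 37.1% of rows all 3 arrays held the same value, and WDR5 itself was tied between the siRNA arrays at 7.90. Quantile normalization of probe set values would make the sorted columns identical, but they differed by up to 0.24. A biweight summary as in MAS5 tied 0.0% of 2000 simulated unchanged probe sets of 25 probes, whereas median polish over 3 arrays tied 79.0%, so median polish is a candidate explanation; the probe noise was assumed, so the simulation does not exclude the biweight. A floor or rounding of low signals is argued against for ties above the highest background row, where 5.5% of rows (291 of 5337) were tied on all arrays, at 268 different values, but stays open for ties at lower levels, as 10.6% of rows in the top quartile of level and 47.6% in the bottom quartile were tied.

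The lower median ratios of the cytoplasmic ribosomal protein list with both siRNAs are a pattern to follow up. Members with the highest control levels did not all share it. Random lists matched on mean level did not reach the medians of the list. The higher of the percentiles was 0.0, so level alone did not give these medians. That percentile is also what picked out the list, so it is no separate test, and compression of the signal was not tested. A loss of short transcripts cannot be judged, since no transcript lengths were used. The mitochondrial ribosomal protein genes, looked at in their place, had a lower median of 0.00 (SD over genes 0.16 with siRNA-1 and 0.21 with siRNA-2). A peculiarity of the 1 control array or culture cannot be told apart from an effect of WDR5 knockdown, since both make the siRNA arrays agree (median of siRNA-1 over siRNA-2 of 0.09) and there is no other control array. An effect of WDR5 on these genes is a hypothesis that this design leaves open.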
